A study of Homo sapiens with 12 samples.

How the data were processed

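RNA sequencing was run on 12 libraries from 2 prostate cancer cell lines, C4-2B and 22RV1, in 4 groups of 3 libraries that the series text describes as biological triplicates. Cells of both lines were grown for 48 h in glutamine-free medium to which L-glutamine was added at 2 mM, without (control) or with the oligonucleotide 56-mer at 50 nM. Total RNA was extracted with a column kit and sequenced by a commercial provider. The replicate numbers used here follow the order of the records, and no paired analysis was possible because the labels give no pairing, culture day or batch.

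The authors deposited 1 normalized table and 1 comparison table per cell line. The normalized values are signal per gene symbol that the authors obtained by dividing read counts by 1 size factor per library, as the values themselves show: every nonzero value is a whole multiple of a single step per library, within a tolerance of 0.01. The counts behind the tables could therefore be worked out, with size factors between 0.732 and 1.18; that of 22RV1 control 1 was 1.0001, so the values of this library lie close to whole numbers without being whole. Each cell line was normalized separately by the authors. The deposited comparison tables give, per the file headers, a mean over the 6 libraries, a log2 fold change of 56-mer over control with its standard error, a Wald score and an unadjusted and an adjusted p-value. In the deposited tables the score is the log2 fold change divided by its standard error, and the sign of the log2 values was checked against the normalized tables. The deposited adjusted p-value is not the Benjamini-Hochberg value of the deposited unadjusted p-value. The processing notes name DESeq without a version. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, so no genomic coordinates are reported and genes carry the symbol of the tables. Each normalized table holds 60315 entries, 1 of them without a symbol, which was left out.

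The recovered reads numbered between 8847368 and 13740386 per library. No counting intervals are given for single genes, because replicate libraries differed by more than counting error and the tests use the spread between replicates. Whether reads of the same RNA molecule were collapsed is not given.

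Within each line, genes with a normalized count of at least 10 in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust variance) on log2 of the normalized count plus 1, 56-mer against control, two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Errors of log2 changes are standard errors from this fit, errors of means are SD, and intervals are 95% confidence intervals. The difference between the lines was tested as the difference of both log2 changes in 1 limma fit of the 12 libraries over the 15527 genes that passed the filter in both lines, in which a constant factor per table and gene cancels. Overlap of calls was compared with the number for independent lists and with Fisher's exact test across genes.

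The tests, the rule for the genes named, 31 gene lists with 630 genes and most alternatives were fixed before the data were examined. The lists cover androgen-regulated genes, glutamine use and amino acid stress, other metabolic and stress programmes, cell cycle, and markers of prostate lineages and of other cell types. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, whose test asks whether the genes of a list move on balance one way. Lists with fewer than 3 tested genes were not tested. Named per line were the 6 largest rises and the 6 largest falls among genes past the threshold with a mean at or above the median of the tested genes and no overlap between groups, 12 genes fixed in advance (among them KLK3, KLK2, TMPRSS2, FKBP5, SLC1A5, GLUL, ASNS, MYC and MKI67), and, where fewer than 12 genes passed, the 6 next genes by unadjusted p. Up to 3 members of each list with at least 3 called members were to be named as well, but no list had that many. Across lines the 6 genes with the smallest adjusted p of the difference were named. Some genes that this rule names are not reported here.

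The alternatives fixed in advance were quantile normalization, columns scaled to equal totals, no filter, a mean of at least 50, pseudocounts of 0.1 and 10, no trend or robust variance, leaving out mitochondrially encoded genes, a spread shared by the 12 libraries, DESeq2 1.42.0 and limma-voom on the recovered reads, an adjusted p threshold of 0.01, an absolute log2 change of at least 1, and leaving out each library. Chosen after seeing the data were the edgeR 4.0.16 quasi-likelihood test on the recovered reads, a lowess correction (span 0.3) of each library for its trend with GC content and transcript length from GENCODE 29, which matched 96.2% of the tested genes in C4-2B and 95.6% in 22RV1, and Benjamini-Hochberg adjustment of the deposited p-values. An analysis of protein-coding genes alone was not run, because the tables give no biotype.

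The pipeline was tested on simulated data with this design. Counts were drawn separately for each gene, without the GC and length trends of the real libraries. In C4-2B limma recovered 34% of 50 genes given a true fold of 1.5, and 58% at a fold of 2. The same shares were 50% and 74% in 22RV1, and 14% and 56% for the difference between lines.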

Results

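RNA sequencing was used to measure transcript levels in C4-2B, a castration-resistant derivative of the LNCaP prostate cancer line, and in 22RV1, another castration-resistant prostate cancer line. Both lines received L-glutamine at 2 mM for 48 h, either alone (control) or together with 50 nM of the 56-mer, an aptamer, that is, a folded single-stranded nucleic acid selected or designed to bind a target. There were 3 libraries in each of the 4 groups. Recovered reads per library numbered 10245014 to 13627140 in C4-2B controls, 12277758 to 12508539 in C4-2B with 56-mer, 11834331 to 13586045 in 22RV1 controls and 8847368 to 13740386 in 22RV1 with 56-mer. Between 20779 and 22686 genes were detected per C4-2B library and between 28342 and 31010 per 22RV1 library. Spearman correlation across genes was 0.977 to 0.982 between C4-2B libraries of 1 group and 0.975 to 0.980 between groups. In 22RV1 it was 0.981 to 0.986 both within and between groups. The 56-mer 1 library stood apart in each line: its log2 values relative to the mean of the line's libraries correlated with transcript length at a Spearman rho of −0.334 across genes with a mean above 100 in C4-2B, and with GC content at −0.583 in 22RV1. In C4-2B the correlation with GC content was 0.304 and 0.318 in 56-mer 2 and 3, against −0.177 in 56-mer 1 and −0.209 to −0.0048 in the controls. Across these genes the log2 change with 56-mer had a Spearman correlation with GC content of 0.241 in C4-2B and −0.188 in 22RV1, and with transcript length of −0.318 and 0.129.

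In C4-2B the comparison asks which transcripts differ when 56-mer is added to cells supplied with glutamine. TXNIP, an arrestin-like protein that binds thioredoxin and limits glucose uptake, rose 1.51-fold, from 829 ± 76.0 to 1251 ± 90.3 normalized read counts (SD, n = 3). CHAC1, a glutathione-degrading enzyme induced by the transcription factor ATF4, rose 1.43-fold, from 1539 ± 92.4 to 2199 ± 93.4. The transcription factor SOX4 fell from 1637 ± 56.2 to 1138 ± 73.0, VEGFA, the angiogenic growth factor, from 6985 ± 249 to 5302 ± 315, and GDF15, a stress-induced cytokine, from 19830 ± 501 to 15440 ± 1188. In total 11 of 16657 tested genes passed, 8 of them higher and 3 lower with 56-mer, with log2 changes of at most 0.60 in size, whereas 2 were higher and 8 lower under quantile normalization and 4 higher and 7 lower with columns scaled to equal totals.

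The fitted log2 changes were 0.60 ± 0.11 for TXNIP (SE, n = 3 per group, limma adjusted p = 0.0254), 0.52 ± 0.088 for CHAC1 (0.0241), −0.53 ± 0.095 for SOX4 (0.0254), −0.40 ± 0.068 for VEGFA (0.0241) and −0.36 ± 0.058 for GDF15 (0.0241). GADD45GIP1, a component of the mitochondrial ribosome, and NUDC, a dynein-associated co-chaperone, rose 1.32-fold each, with adjusted p of 0.0361 and 0.0395. The small heat shock protein HSPB1 rose 1.21-fold, from 26410 ± 1078 to 32010 ± 1025 normalized read counts (adjusted p = 0.0254). Of the mitochondrially encoded genes, MT-ND2, a subunit of respiratory complex I, rose 1.21-fold (adjusted p = 0.0254) and MT-CO3, a subunit of cytochrome c oxidase, rose 1.18-fold (0.0361), although under quantile normalization 6 of the 13 genes of this family were higher. RPLP0, a protein of the ribosomal stalk, rose 1.18-fold (0.0446). RPLP0 and MT-CO3 lie outside the naming rule and were chosen after their values were seen. TXNIP, CHAC1, SOX4, VEGFA and GDF15 also passed under quantile normalization, but GADD45GIP1 (log2 change 0.33, adjusted p = 0.0785), NUDC (0.34, 0.0966), HSPB1 (0.14, 0.260), MT-ND2 (0.14, 0.260), MT-CO3 (0.097, 0.264) and RPLP0 (0.059, 0.734) did not. With equal totals GADD45GIP1, NUDC, MT-CO3 and RPLP0 lost the call, and after correction for GC content and length GADD45GIP1, NUDC and HSPB1 did. Among the genes next in p, none of which passed, the glucose transporter SLC2A1 had a log2 change of −0.50 (adjusted p = 0.0540), MT-CYB 0.22 (0.0828), the mitophagy receptor BNIP3 −0.28 (0.106), the spermidine synthase SRM 0.33 (0.106) and NAXE, which repairs hydrated NADH and NADPH, 0.35 (0.106). At an unadjusted p under 0.05 there were 1486 genes, where 833 are expected by chance, and in 14.7% of genes the groups did not overlap, where chance gives 10%. With limma 0 genes passed when any of controls 1 to 3, 56-mer 2 or 56-mer 3 was left out (1024 to 1500 at an unadjusted p under 0.05), whereas 81 passed without 56-mer 1, all 11 among them. With edgeR 0 genes passed (1403 at an unadjusted p under 0.05), and with DESeq2 86 did.

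**Figure D1:**
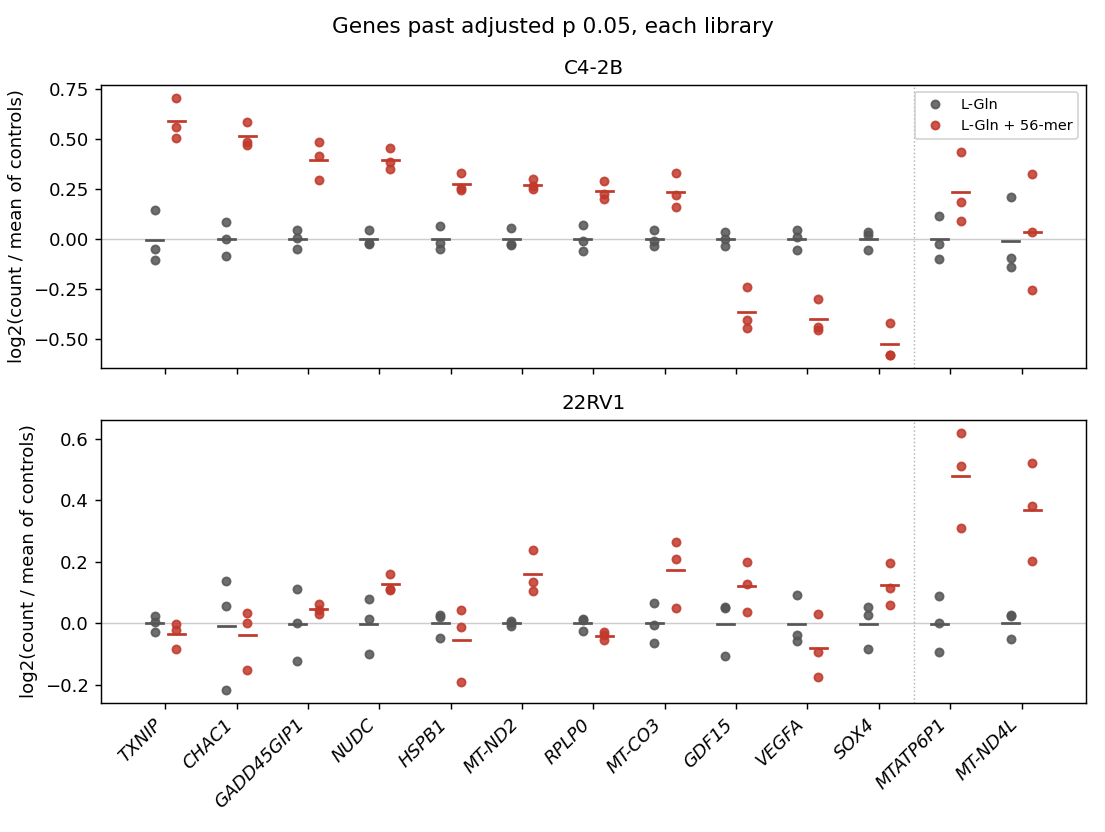
Normalized read counts of the 13 genes that passed the test in either line, plotted for each library as the log2 ratio to the mean of that line's 3 control libraries; short bars are group means, and the dotted line separates the 11 genes called in C4-2B from the 2 called in 22RV1. In C4-2B the 3 libraries with 56-mer lie above the controls for TXNIP and CHAC1 and below them for SOX4, VEGFA and GDF15.

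Among the lists fixed in advance, genes induced by low oxygen were lower with 56-mer in C4-2B. Of the 20 tested genes of the hypoxia list 17 had a lower mean, with a median log2 change of −0.21, and VEGFA passed over all genes. Adjusted over the list alone, 6 genes fell, among them VEGFA, SLC2A1, BNIP3 and the hexokinase HK2 (−0.38 ± 0.11). Nuclear-encoded subunits of oxidative phosphorylation were higher in 27 of 32 cases, with a median of 0.15, although none passed over all genes and none adjusted over the list alone. Camera gave an adjusted p of 0.00207 for hypoxia and 0.0152 for oxidative phosphorylation. With an estimated correlation their unadjusted p were 0.0122 and 0.400, and neither list passed after adjustment. The call of oxidative phosphorylation was also lost without control 2 (adjusted p = 0.0806), control 3 (0.255) or 56-mer 1 (0.668, with a median of 0.067), and fry called no list. The 100 most abundant nuclear genes had a median log2 change of 0.11 in C4-2B.

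The 13 protein-coding genes of the mitochondrial genome had a median log2 change of 0.12 in C4-2B, with 11 higher, and under quantile normalization 6 were higher; without 56-mer 1 the median was 0.063 (camera adjusted p = 0.649). The list did not pass (camera adjusted p = 0.0715), 2 of its genes rose over all genes and 6 adjusted over the list alone. All entries whose symbol marks them as mitochondrially encoded, not only these 13 genes, took 7.65% ± 0.0492 of reads in controls and 8.03% ± 0.236 with 56-mer (SD, n = 3). The exact two-sided permutation p of this difference was 0.1, the smallest that 3 against 3 libraries allow. Glycolysis genes had a median of −0.072 (adjusted p = 0.0915), and 5 of 22 fell when adjusted over the list alone. SLC2A1 and HK2, named above under hypoxia, also belong to the glycolysis list. After correction for GC content and length, chosen after seeing the data, the list passed (0.0163; unadjusted p = 0.165 with an estimated correlation), and under quantile normalization its median was −0.12. Stem cell markers had a median of −0.34 over 7 tested genes (0.0915), which was −0.18 without 56-mer 2, and the list passed without 56-mer 1 (0.0300); with an estimated correlation over all 6 libraries its unadjusted p was 0.145. Ribosome biogenesis and MYC targets had a median of 0.10 over 25 (0.113), with BOP1, a processing factor of the large ribosomal subunit, higher adjusted over the list alone.

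The androgen-induced genes fixed in advance and given here did not pass in C4-2B. KLK3, which encodes prostate-specific antigen, had a log2 change of 0.059 (95% interval −0.077 to 0.20), KLK2 −0.057 (−0.22 to 0.11), TMPRSS2 −0.039 (−0.17 to 0.094) and FKBP5 −0.026 (−0.26 to 0.21). The glutamine transporter SLC1A5 had a log2 change of 0.051 (−0.10 to 0.20), the glutamine synthetase GLUL −0.015 (−0.19 to 0.16) and the asparagine synthetase ASNS −0.043 (−0.56 to 0.47). MYC had −0.11 (−0.28 to 0.067) and the proliferation marker MKI67 −0.026 (−0.21 to 0.15).

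In 22RV1, where the comparison asks the same question, the transcripts that passed belong to or resemble the mitochondrial genome. MT-ND4L, a subunit of respiratory complex I, rose 1.29-fold, from 4431 ± 132 to 5743 ± 627 normalized read counts (SD, n = 3). MTATP6P1, a nuclear pseudogene that resembles mitochondrial MT-ATP6 closely enough to share its reads, rose 1.40-fold, from 1429 ± 91.5 to 2001 ± 216. All 13 protein-coding genes of the mitochondrial genome had a higher mean with 56-mer, by a median of 0.16 on the log2 scale; under quantile normalization 8 of 13 were higher, with a median of 0.091. All entries whose symbol marks them as mitochondrially encoded, not only these 13 genes, took 5.48% ± 0.143 of reads in controls and 6.09% ± 0.388 with 56-mer (SD, n = 3). The exact two-sided permutation p of this difference was 0.1, the smallest possible.

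Of 20517 tested genes these 2 passed, both with a limma adjusted p of 0.0119 and with log2 changes of 0.37 ± 0.066 for MT-ND4L and 0.48 ± 0.084 for MTATP6P1 (SE). The list of mitochondrially encoded genes had a camera adjusted p of 4.23e-06, with 1 gene passing over all genes and 12 adjusted over the list alone, and its p was 0.101 with an estimated correlation. The genes next in p did not pass. MT-CYB, the cytochrome b of complex III, had a log2 change of 0.23 (adjusted p = 0.0724), the xenobiotic-metabolizing enzyme CYP1A1 0.43 (0.0724), MT-CO1 0.20 (0.484), the mitochondrial import factor TIMM21 −0.54 (0.613), the transcript AC092120.3 −1.80 (0.613) and the lysosomal fucosidase FUCA1 0.64 (0.613). At an unadjusted p under 0.05 there were 803 genes, where 1026 are expected by chance, and in 9.03% of genes the groups did not overlap, where chance gives 10%. With limma 0 genes passed when any of controls 1 to 3 or 56-mer 2 was left out (632 to 868 at an unadjusted p under 0.05), and 5 and 11 genes passed without 56-mer 1 and 56-mer 3, both genes among them each time.

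Stem cell markers were higher in 10 of 11 cases in 22RV1, with a median of 0.21 (camera adjusted p = 0.0151, and an unadjusted p of 0.0478 with an estimated correlation that did not pass after adjustment). No member passed over all genes and none adjusted over the list alone. The hyaluronan receptor CD44 had a log2 change of 0.23, KLF4, a pluripotency factor also expressed in differentiated epithelia, 0.29, and the efflux pump ABCG2 0.25; these examples were chosen after their values were seen. The list lost its call without control 3 (adjusted p = 0.268), 56-mer 1 (0.131) or 56-mer 2 (0.107).

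In 22RV1 too, the androgen-induced genes given here did not pass. KLK3 had a log2 change of −0.042 (95% interval −0.23 to 0.15), KLK2 −0.056 (−0.24 to 0.13), TMPRSS2 −0.0029 (−0.26 to 0.25) and FKBP5 −0.042 (−0.18 to 0.095). ASNS, at 147 ± 37.6 normalized read counts in controls and 204 ± 11.6 with 56-mer (SD, n = 3), had a log2 change of 0.51 (95% interval 0.13 to 0.88) that did not pass over all genes (limma adjusted p = 0.9996). SLC1A5 had a log2 change of −0.015 (−0.17 to 0.14), GLUL 0.12 (−0.070 to 0.30), MYC 0.016 (−0.13 to 0.16) and MKI67 0.048 (−0.088 to 0.18).

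**Figure D2:**
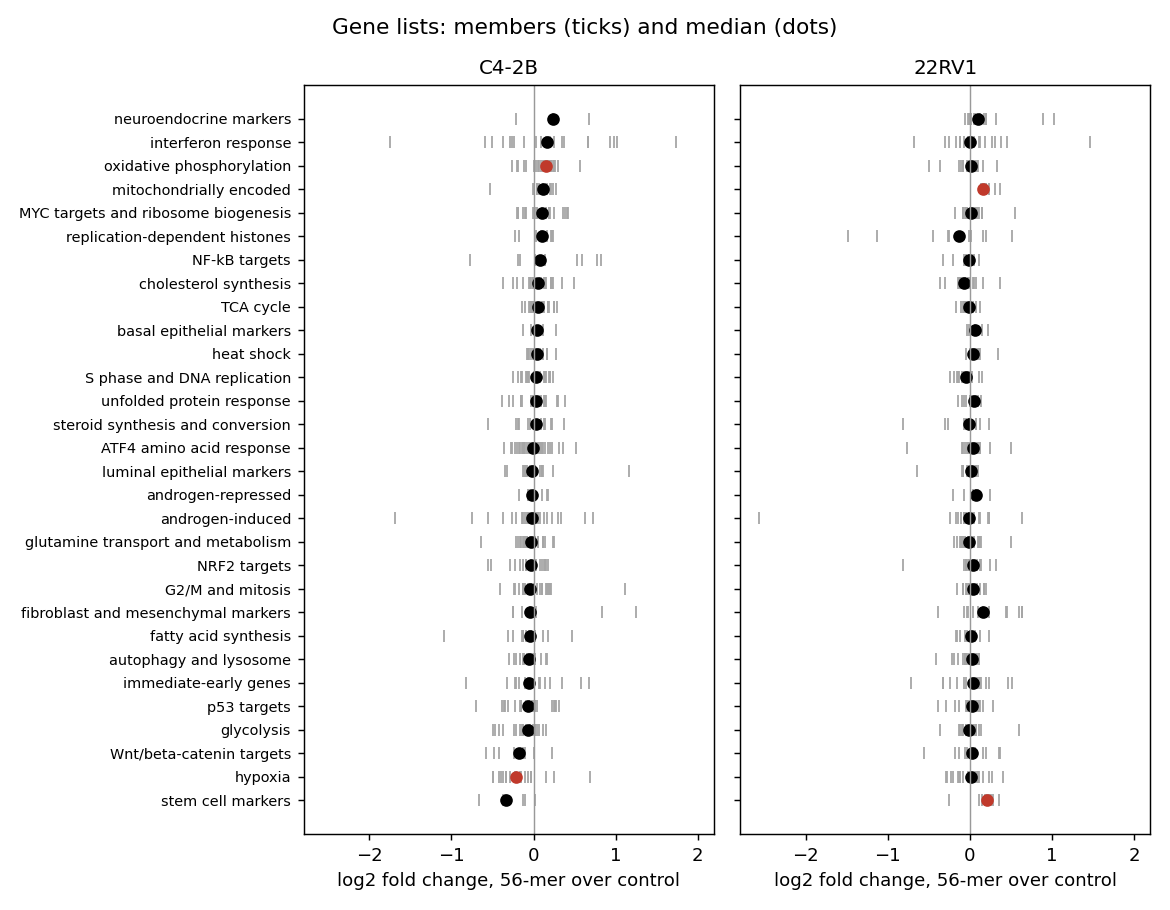
Log2 change with 56-mer for the genes of the 30 tested lists in C4-2B and 22RV1; each tick is a gene, each dot the median of a list, and red marks lists with a camera adjusted p under 0.05. Hypoxia (median −0.21) and oxidative phosphorylation (0.15) are marked in C4-2B, and mitochondrially encoded genes (0.16, with 8 of 13 higher under quantile normalization) and stem cell markers (0.21) in 22RV1. None of these lists passed with an estimated correlation.

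The remaining lists passed in neither line, and their medians are given as C4-2B then 22RV1 on the log2 scale. Androgen-induced genes had −0.025 and −0.0068 over 32 genes each, and androgen-repressed genes −0.014 and 0.069. Genes of glutamine transport and metabolism had −0.026 and −0.0078 over 27 each. The ATF4 amino acid response had −0.0071 and 0.042, and in C4-2B its members split: CHAC1 rose, GDF15 fell, and adjusted over the list alone 3 were higher and 2 lower. The unfolded protein response had 0.033 and 0.046, heat shock genes 0.036 and 0.034, with HSPB1 called in C4-2B, and NRF2 targets −0.036 and 0.039. Interferon response genes had 0.16 and 0.0055, NF-kB targets 0.079 and −0.0064, and immediate-early genes −0.059 and 0.044. Genes of G2/M had −0.041 and 0.044, those of S phase 0.035 and −0.044, p53 targets −0.065 and 0.030, and replication-dependent histones 0.10 and −0.13. Cholesterol synthesis genes had 0.059 and −0.077, fatty acid synthesis genes −0.047 and 0.0094, genes of the TCA cycle 0.052 and −0.016, steroid synthesis genes 0.024 and −0.0063, and autophagy and lysosome genes −0.057 and 0.023. Luminal epithelial markers had −0.014 and 0.018, and adjusted over the list alone the pioneer factor FOXA1 (−0.35) was lower and the keratin KRT18 (0.24) higher in C4-2B. There FOXA1 passed over all genes under quantile normalization, with equal totals and after the GC and length correction, and KRT18 in none of these. Basal epithelial markers had 0.039 and 0.063, neuroendocrine markers 0.24 over 3 genes and 0.094 over 14, Wnt targets −0.18 and 0.022, and fibroblast and mesenchymal markers −0.047 and 0.16, the last with a camera adjusted p of 0.101. In 22RV1 hypoxia genes had a median of 0.016 over 21, glycolysis genes −0.0085, oxidative phosphorylation genes 0.011, and ribosome biogenesis and MYC targets 0.018. Markers of leukocytes and endothelium could not be tested as a list, since 2 (CD68 and VWF) passed the filter in C4-2B and 1 (CD68) in 22RV1.

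**Figure D3:**
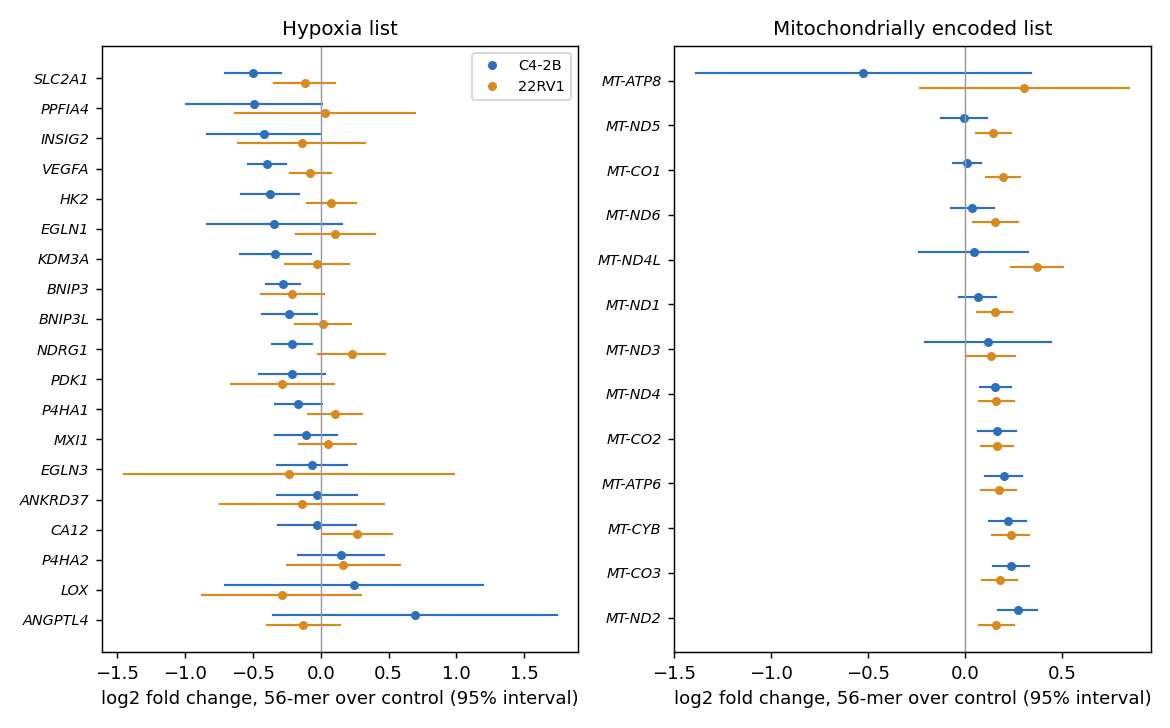
Log2 change with 56-mer (horizontal axis, with 95% intervals) in C4-2B (blue) and 22RV1 (orange) for the 19 hypoxia genes tested in both lines and the 13 protein-coding genes of the mitochondrial genome. VEGFA is at −0.40 in C4-2B and −0.078 in 22RV1, and MT-ND4L is at 0.043 in C4-2B and 0.37 in 22RV1; under quantile normalization 6 (C4-2B) and 8 (22RV1) of the 13 mitochondrial genes were higher.

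Both lines received the same dose for the same time, so the effects were set side by side. The hypoxia list differed between the lines (camera adjusted p = 0.0415). Over 19 genes the change in 22RV1 exceeded that in C4-2B by a median of 0.27 on the log2 scale. With an estimated correlation the unadjusted p was 0.0196 and the adjusted p 0.447, so the call was lost. The log2 changes of the lines had opposite trends with GC content and with length. The list difference was not tested after correction for these or with a library left out. The stem cell markers, with a median difference of 0.38 over 7 genes, did not pass (0.0506), nor did any other list. For single genes limma called 0 of 15527, with 1227 at an unadjusted p under 0.05 where 776 are expected by chance; 5 passed with no filter.

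The 6 genes with the smallest adjusted p of the difference were IGFBPL1, TXNIP, GDF15, SOX4, RPLP0 and KAT6A, none past the threshold, although IGFBPL1, TXNIP, GDF15 and SOX4 passed after correction for GC content and length, and IGFBPL1, TXNIP and GDF15 passed with no filter. IGFBPL1, an insulin-like growth factor binding protein-like gene, had 23.4 ± 6.37 normalized read counts in C4-2B controls and 0.325 ± 0.563 with 56-mer, against 95.5 ± 16.9 and 106 ± 28.0 in 22RV1 (SD, n = 3). The limma adjusted p of the difference was 0.0908. Within C4-2B it did not pass (limma adjusted p = 0.396), and its 56-mer values were 0, 0 and 0.974. The test of the difference uses 1 spread for the 12 libraries. Its SE was therefore 0.74 for IGFBPL1, against 1.37 in C4-2B alone, and 0.20 against 0.22 for KAT6A. The difference, 22RV1 minus C4-2B, was −0.63 ± 0.11 for TXNIP (0.0961), 0.49 ± 0.090 for GDF15 (0.109), 0.65 ± 0.12 for SOX4 (0.112), −0.28 ± 0.061 for RPLP0 (0.373) and 0.91 ± 0.20 for the histone acetyltransferase KAT6A (0.373). Leaving out C4-2B control 1, control 3, 56-mer 1 or 56-mer 3 gave 2, 3, 11 and 8 genes past the threshold. Without C4-2B control 2, C4-2B 56-mer 2 or any single 22RV1 library there were 0.

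No gene passed in both lines, where independent lists would share 0.00103 in the upward direction. After correction for GC content and length, chosen after seeing the data, MT-CYB, MT-ND2 and MT-ATP6 passed in both. At an unadjusted p under 0.05, 13 genes were higher in both lines, where 12.9 are expected for independent lists (Fisher's exact p across genes 0.886). Of these 13, MT-CO2, MT-CYB, MT-ND2, MT-ND4, MT-ATP6, MT-CO3, MT-TS1 and MTATP6P1 belong to or resemble the mitochondrial genome, and the others included NAA10, ZNF414, PCYT1A and LPCAT4, all chosen after their values were seen. There were 9 genes lower in both, where 13 are expected (0.316). Across genes, which are not independent replicates, the log2 changes of the lines had a Pearson correlation of −0.017 and a Spearman correlation of −0.055. Over the 3833 more abundant genes, with a mean above 500 normalized read counts in both lines, these were −0.113 and −0.136.

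In the deposited comparison tables of the authors, 0 of 28774 genes in C4-2B and 0 of 38270 in 22RV1 had an adjusted p under 0.05, with 1438 and 792 at an unadjusted p under 0.05. Benjamini-Hochberg adjustment of the deposited p-values gave 17 genes in C4-2B, 10 higher and 7 lower, of which 10 were also called by limma here, among them VEGFA and TXNIP. In 22RV1 it gave CYP1A1, MT-ND4L and MTATP6P1. The deposited log2 changes and those fitted here had a Pearson correlation across genes of 0.934 in C4-2B and 0.958 in 22RV1.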

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

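The tests of single libraries, of GC content and length, and of the mitochondrial share over both lines were chosen only after the result was seen.

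The hypoxia list was picked out because its response differed between the lines by a test of the difference itself, with a median difference of 0.27 on the log2 scale. In C4-2B the list's median was −0.21, and 2 technical explanations and the choice of genes were weighed. After correction for GC content and length the median was −0.17 and the list still passed at the preset correlation, and with each library left out the median closest to 0 was −0.17, with camera adjusted p from 0.00274 to 0.0349, which argues against a GC or length trend or a single library as the whole source, although with an estimated correlation the list's adjusted p was 0.367. A second set of 24 oxygen-regulated genes that shares none with the list, among them WSB1 and BHLHE40, had a median of −0.18 (camera p = 0.000706; adjusted p = 0.00106 over the 6 added sets; with an estimated correlation the unadjusted p was 0.0269 and the adjusted p 0.161, so the call was lost). A response to 56-mer in C4-2B may account for the pattern as a hypothesis, but a difference in culture density or oxygen between dishes stays open, since the labels record neither.

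In 22RV1 the mitochondrially encoded transcripts were higher. In both lines the share of reads from all mitochondrially encoded entries was higher in every library with 56-mer than in any control. After correction for GC content and length the list's median was 0.17, and the smallest median with a library left out was 0.12, both with the list past the threshold at the preset correlation, which argues against those trends and against a single library, although with an estimated correlation the list's p was 0.101 (0.0553 after the correction) and no call held. The authors' scaling would also lift other abundant transcripts, but the 100 most abundant nuclear genes had a median of 0.0146 (SD 0.053) in 22RV1; in C4-2B the same measure was 0.11, close to the mitochondrial median there. Permuting labels within both lines gave an exact p of 0.005 for the share (2 of 400 arrangements), which is fixed at the smallest possible value once no libraries overlap and so does not decide whether the spread arose by chance. A response to 56-mer is consistent with these values as a hypothesis, while a difference in RNA extraction or library preparation between the groups was not tested and stays open, and quantile normalization, which pins the most abundant genes, left 8 of 13 genes higher.

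Replicate counts varied more than counting error, with a mean ratio of variance to mean of 3.36 or more in every group even among genes with 1 to 5 reads. Variation between cultures by the same small share of the mean in every gene would bring that ratio near 1 at such counts. That form of variation cannot be the whole source. A larger share in weakly expressed genes was not tested, so variation between cultures cannot be excluded. Counting both mates of a read pair would leave few odd counts, but at least 50.4% of the counts were odd in each library. Several reads per RNA molecule may contribute: the median count of genes seen in 1 of 3 libraries was 4 in both C4-2B groups. It was 2 in both 22RV1 groups, below the value of 3 set in advance, so over both lines this cannot be told from other sources. Of these genes 12.1% and 18.5% had a count of 1 in C4-2B controls and with 56-mer, and 28.3% and 29.6% in 22RV1. The commonest low count was 3 or 4 in the C4-2B libraries other than 56-mer 1, where it was 1, and 1 or 2 in 22RV1. No biological explanation was tested.

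The 6 libraries of a line can be split in 10 ways, the real one included, too few for a share under 0.05. In C4-2B the real split called 11 genes, the highest other 1, and 2 lists, the highest other 1. In 22RV1 the real split called 2 genes, the highest other 3, and 2 lists, the highest other 2, so 2 of the 10 splits gave as many in each case. For the difference between lines the real split called 0 genes (highest other 2), a count that all 100 of the 100 splits reach by construction, so it says nothing. For lists, 43 of 100 gave at least the real 1 list (highest other 4), so chance cannot be excluded for the difference of the hypoxia list.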

How the results depend on the processing

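The edgeR test, the GC and length correction and the adjustment of the deposited p-values were tests chosen only after the results were seen. The 11 genes called in C4-2B became 34 with no filter, 86 with DESeq2 and 43 with a spread shared by the 12 libraries. With no trend or robust variance 1 gene passed, which was not among the 11. The count was 0 at an adjusted p under 0.01, 0 at an absolute log2 change of at least 1 and 0 with edgeR. It was 20 after the GC and length correction (8 of the 11 among them) and 17 from the deposited p-values. Leaving out 1 library gave 0 to 81. The share that rose, 8 of 11, was 2 of 10 under quantile normalization and 4 of 11 with equal totals, scalings that moved the median of all genes by 0.038 and −0.041. The 2 genes called in 22RV1 became 11 with no filter, 0 with no trend or robust variance, 1 without mitochondrially encoded genes, 0 with a shared spread, 0 under either stricter threshold and 7 after the GC and length correction; leaving out 1 library gave 0 to 11. The 2 lists called in each line became 0 with an estimated correlation and 0 with fry, and leaving out 1 library gave 1 to 2 in C4-2B and 1 to 3 in 22RV1. The difference between lines went from 0 genes to 5 with no filter and 5 after the GC and length correction, and from 0 to 11 with 1 library left out. Shared calls went from 0 to 3 after that correction (MT-CYB, MT-ND2 and MT-ATP6). The threshold changes and the removal of genes act by construction; elsewhere the cause was not tested. For single genes and lists named, 1170 results under the alternatives fixed in advance kept their side of the threshold. Of the others, 107 lost the call and 45 gained one. Under added alternatives these were 202, 15 and 13. No result that passed in either setting changed direction. A change of sign without a call in either setting was counted as kept, as for KLK3 in C4-2B under quantile normalization (log2 change −0.0076). Protein-coding genes alone were not run. In C4-2B limma recovered 34% of simulated genes at a fold of 1.5, so changes of that size or smaller could be missed.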

Other observations

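The adjustment of the deposited p-values and the tests of the added sets under other scalings or without a library were chosen only after the result was seen; the 6 added sets and ARRDC4 were picked after the calls above had been seen, with predictions written before their own results.

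In C4-2B, genes of ribosomal proteins and of the proteasome passed with camera at its preset correlation but not with an estimated one. Of 79 cytosolic ribosomal protein genes 75 had a higher mean, with a median log2 change of 0.14 (camera adjusted p over the 6 added sets 2.65e-08); RPLP0 passed over all genes and 14 adjusted over the set alone. Without 56-mer 1 the median was 0.058 (adjusted p = 0.0128), after correction for GC content and length it was 0.094, and under quantile normalization 58 of 79 were higher, with a median of 0.048. Mitochondrial ribosomal protein genes were higher in 63 of 76 cases, with a median of 0.13 (1.01e-06), and proteasome subunit genes in 26 of 31, with a median of 0.13 (1.60e-05) that was 0.078 without 56-mer 1 (0.0122). The 100 most abundant nuclear genes had a median of 0.11 in C4-2B, with 84 higher. With an estimated correlation the adjusted p of the 3 sets were 0.353, 0.265 and 0.265. In 22RV1 the same sets had medians of −0.030 (adjusted p = 0.159), −0.020 (0.416) and −0.038 (0.338), but the cytosolic set passed as lower without control 1 (−0.061, 0.0138) or 56-mer 3 (−0.062, 0.0389), and under quantile normalization its unadjusted camera p was 0.0039.

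With the preset correlation the difference between the lines passed for cytosolic ribosomal proteins (median −0.17, 22RV1 minus C4-2B, adjusted p = 5.57e-10), mitochondrial ribosomal proteins (−0.14, 5.33e-06), proteasome subunits (−0.14, 5.33e-06) and the second oxygen-regulated set (0.17, 0.0157). With an estimated correlation the adjusted p were 0.239, 0.155, 0.155 and 0.137, so none of these calls held. The second oxygen-regulated set had an adjusted p of 0.962 in 22RV1.

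Targets of the aryl hydrocarbon receptor, tested because CYP1A1 was among the genes next in p in 22RV1, did not pass in 22RV1 (adjusted p = 0.159, 8 of 11 higher, median 0.045) or in C4-2B (0.298). In 22RV1 their median was 0.13 without control 1 (0.0574), 0.12 without control 2 (0.557), 0.073 without control 3 (0.481) and 0.015 without 56-mer 2 (0.683). Without 56-mer 3 it was 0.15 and the set passed (0.0348). CYP1A1 itself belongs to the set, so these values partly restate the gene that prompted the test. Its unadjusted limma p in 22RV1 was 1.41e-05, and the next smallest in the set was 0.113, for TIPARP. Targets of YAP and TEAD did not pass in C4-2B (0.121, median 0.0029) or 22RV1 (0.860), but in C4-2B they passed as lower without 56-mer 1 (0.0399, median −0.059). TXNIP is induced by the glucose sensor MondoA, and so is ARRDC4, whose log2 change in C4-2B was 0.054 (95% interval −0.69 to 0.80, too wide to decide whether a MondoA response is a candidate explanation).

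The adjusted p-values in the deposited tables have minima of 0.447 in C4-2B and 1 in 22RV1, whereas Benjamini-Hochberg adjustment of the unadjusted values beside them gives minima of 0.000303 and 0.0029. How the deposited adjusted values were made was not given.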
